A study of Drosophila melanogaster with 9 samples.

How the data were processed

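Ovary RNA was isolated with TRIzol, and libraries were made with a stranded TruSeq mRNA kit and sequenced on a HiSeq 2500, per the labels' protocols. The submitters' processing notes name Trimmomatic 0.36, FastQC, HISAT2 2.0.4, SAMtools 0.1.19, HTSeq and the genome build BDGP6, without saying what each did. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Values of overlapping, antisense or near-identical genes are uncertain for that reason. The authors deposited 1 file of raw read counts per gene for each of the 9 libraries, with no normalization. The files held 17558 gene identifiers and 0 entries that name no gene. Symbols and coordinates came from an Ensembl annotation of BDGP6.54, a later release of the BDGP6 assembly series; 17252 identifiers matched it, and the 306 others, with 5.00% of counts, are named nowhere.

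Groups came from the genotype in the labels. Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 8642, and libraries were scaled by TMM. The quasi-likelihood test was fitted to all 9 libraries with 1 coefficient per genotype, so that groups share 1 estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method over genes tested, with a threshold of 0.05. The common dispersion was 0.0404, a biological coefficient of variation of 20.1%. A standard error is the absolute log2 fold change divided by the square root of F. Folds against a group at 0 counts use a floor of 3 counts over the group, and those against 1 to 3 counts have exact 95% binomial intervals; both cover counting error only. Depth was 31.8 to 43.6 M (1e6) counts, so 1 CPM is about 31 counts or more.

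Gene lists numbered 38 and were written, with the design, the alternatives and the rule for named genes, before the data were examined. They were tested by camera (preset correlation 0.01) where at least 5 members were tested, which left 35 lists, adjusted together within a comparison. All calls of lists by camera were lost with an estimated correlation. The Turandot list had 0 of 8 members tested, the digestive tract list 1 of 40 and the testis list 3 of 33. The other eggshell list holds 2 misplaced members, Mcm10 and Col4a1, found after it was fixed and left in place.

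Genes were named by rule: Moe and w; every measured heat shock list member; up to 12 genes each way by mean log2 fold change among those called against both heterozygotes; the 5 highest and 5 lowest called genes per comparison whose groups do not overlap; and up to 4 members of lowest adjusted p per described list. Of the genes the rule takes, 1 called against both heterozygotes is not described here, the Hsp70 copies are given as a sum, and most list members that were not called are left unnamed. The parts on genes called against both heterozygotes and on the 5 highest and lowest need a mean of at least 1 CPM. Groups that do not overlap arise by chance in 10% of genes with 3 against 3.

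The procedure was tested on simulated data with 8547 genes kept, of which 100 were changed 2-fold and 100 changed 4-fold. Against the null heterozygote, 68% and 86% were recovered with 4.94% of calls false. Against the NES heterozygote, 66% and 85% were recovered with 4.43% false. With no simulated change between heterozygotes, 0 genes were called. A simulated list of 17 genes lowered 2-fold had camera adjusted p of 2.97e-28 and 4.41e-28 against the 2 heterozygotes and 0.997 between them. Each gene was drawn independently, without variation shared across genes of a library. These values therefore do not give the error rates in the real libraries. Replicates were compared for duplicates: chi-square per degree of freedom lay between 17.7 and 310, so each library counts once.

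Alternatives were DESeq2 1.42.0 and its size factors, scaling without eggshell, yolk and mitochondrial genes, library size alone, no low-count filter, a stricter filter (mean of at least 5 CPM), fits with only the groups compared, the replicate number as a block, a test against a 1.5-fold change, each library left out in turn, and for lists an estimated correlation and fry. Values given for fry are those of its directional test unless stated. Chosen after seeing the data were the log2 share of counts in eggshell genes, without yolk genes, as a covariate and leaving out null heterozygote replicates 1 and 3.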

Results

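Gene expression was measured by RNA sequencing in ovaries of 3-day-old Drosophila melanogaster females, with 10 females per sample. The rearing temperature was 25 °C for all samples, and the groups differ by genotype, not by a heat treatment. Moesin, encoded by Moe, is the single fly member of the ERM family, proteins that link actin filaments to the plasma membrane, and the series asks whether heat shock genes depend on it. There were 9 libraries in 3 groups of 3. The null heterozygote carried the moe[G0415] allele over a w1118 chromosome, the NES heterozygote carried moe[NES] over w1118, and the mutant carried moe[NES] over moe[G0415]. Total counts, in M (1e6), ranged from 31.8 in null heterozygote replicate 2 to 43.6 in mutant replicate 1. The labels do not say that replicates came from separate crosses, so p-values measure the spread between these samples. Levels are TMM-scaled counts per 1e6 (CPM), as mean ± SD with n = 3 per group.

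Libraries differed in their share of eggshell and yolk transcripts, which are made in mid and late egg chambers. Eggshell and yolk genes took 1.33%, 5.35% and 1.52% of counts in null heterozygote replicates 1, 2 and 3. They took 6.07%, 4.19% and 5.40% in the mutant replicates and 2.91%, 5.54% and 4.13% in the NES heterozygote replicates. Null heterozygote replicates 1 and 3 therefore stood apart from the other 7 libraries. The first principal component, with 46.1% of the variance, placed these 2 libraries at one end (-46.15 and -44.18). NES heterozygote replicate 1 came next (-21.95), and it also had the next lowest share. The second component set the NES heterozygote replicates (25.9, 23.06 and 24.67) apart from the other genotypes, whose libraries lay between -16.81 and -6.28. Null heterozygote replicate 2 was at one end of the third component (-35.23). The next library on that side was NES heterozygote replicate 2 (-13.99). Null heterozygote replicate 2 was thus also set apart, on a different component from replicates 1 and 3.

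**Figure D1:**
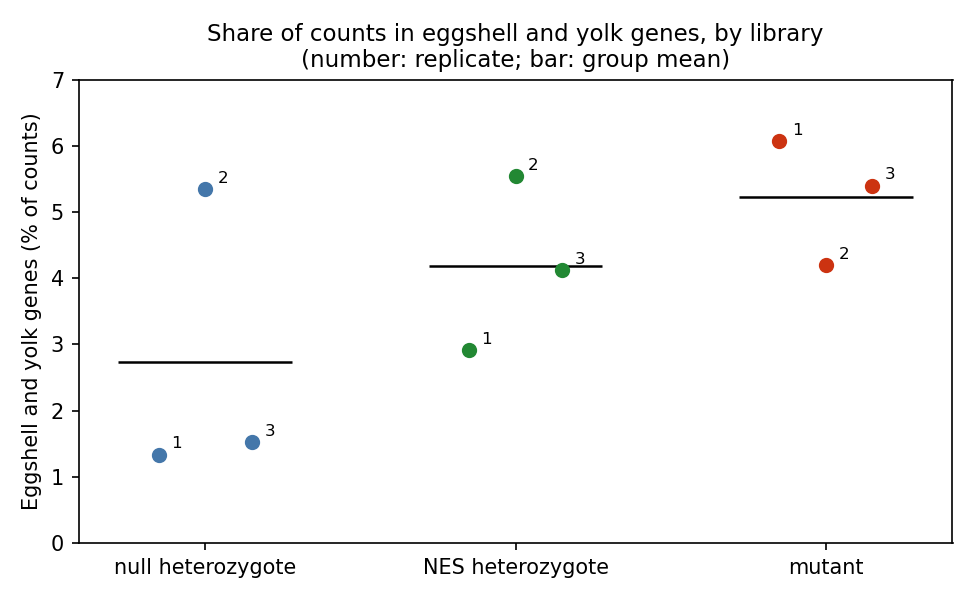
Percent of all counts assigned to eggshell and yolk genes (y axis) in each library of the 3 groups (x axis), with the group mean as a bar and the replicate number beside each point. Null heterozygote replicates 1 and 3 lie at 1.33% and 1.52%, below the other 7 libraries, which lie between 2.91% and 6.07%.

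The target gene was examined first, as a check of the labels. Moe (FBgn0011661, BDGP6.54 annotation, chromosome X, 8873012 to 8898332, minus strand) was at 388 ± 44.7 CPM in the null heterozygote, 694 ± 75.02 in the NES heterozygote and 409 ± 28.3 in the mutant. It was lower in the mutant than in the NES heterozygote (log2 fold change -0.76, SE 0.11, edgeR adjusted p = 0.0218) and higher in the NES than in the null heterozygote (0.84, SE 0.11, adjusted p = 0.0103). The mutant and the null heterozygote differed by 0.08 (SE 0.11, adjusted p = 0.671). The eye colour gene w (FBgn0003996, chromosome X, 2790599 to 2796466), often carried as a marker by P elements, was at 26.4 ± 8.67, 1.09 ± 0.746 and 39.3 ± 3.04 CPM in the null heterozygote, NES heterozygote and mutant. Its log2 fold change against the NES heterozygote was 5.17 (SE 0.49, adjusted p = 0.00259) in the mutant, and -4.60 (SE 0.48, adjusted p = 0.00374) for the NES against the null heterozygote.

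The comparison of the mutant with the null heterozygote asks what changes when the wild-type copy of Moe is replaced by moe[NES]. Heat shock genes leaned lower in the mutant, with 1 member past the threshold over all genes. Hsp26, a small heat shock protein gene (FBgn0001225, chromosome 3L, 9376418 to 9377427), fell from 1188 ± 81.6 to 680 ± 30.1 CPM (log2 fold change -0.80, SE 0.12, adjusted p = 0.0198). It was the 1 member of the inducible heat shock list, of 17 tested, that passed over all genes; 8 were lower when adjusted over the list alone, and 16 of 17 had a negative log2 fold change. The list's median was -0.97 (camera adjusted p = 2.54e-08, but adjusted p = 0.73 with an estimated correlation and 0.155 by fry). The 6 Hsp70 copies, which can share reads, each count as a member. Without them the median was -0.422. The list test was not run with the copies as 1 member. The log2 fold change was -1.24 (SE 0.44) for Hsp23, -1.31 (SE 0.59) for Hsp68, -1.21 (SE 0.29) for the co-chaperone gene stv -0.42 (SE 0.14) for DnaJ-1 and -0.20 for the noncoding lncRNA:Hsromega (-0.32 against the NES heterozygote), none past the threshold over all genes. Hsp83, the fly Hsp90 gene, was at 4640 ± 757 and 4682 ± 76.3 CPM. Its log2 fold change of 0.01 (SE 0.12) turned negative with library size alone as the scaling.

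The 6 nearly identical Hsp70 copies are uncertain one by one, because reads can be split or lost among them. Summed, they were at 47.5 ± 4.10 CPM in the null heterozygote, 45.7 ± 21.4 in the NES heterozygote and 13.5 ± 6.89 in the mutant. The summed log2 fold change was -1.82 against the null heterozygote (SE 0.42, adjusted p = 0.0974) and -1.76 against the NES heterozygote (SE 0.42, adjusted p = 0.13). Hsp22 had 0 counts in all 9 libraries and CG4456 had at most 4 in any. Hsp22 lies inside CG4456 on the same strand (chromosome 3L, 9372931 to 9374964 within 9372722 to 9374964), so reads there can be counted for neither gene.

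**Figure D2:**
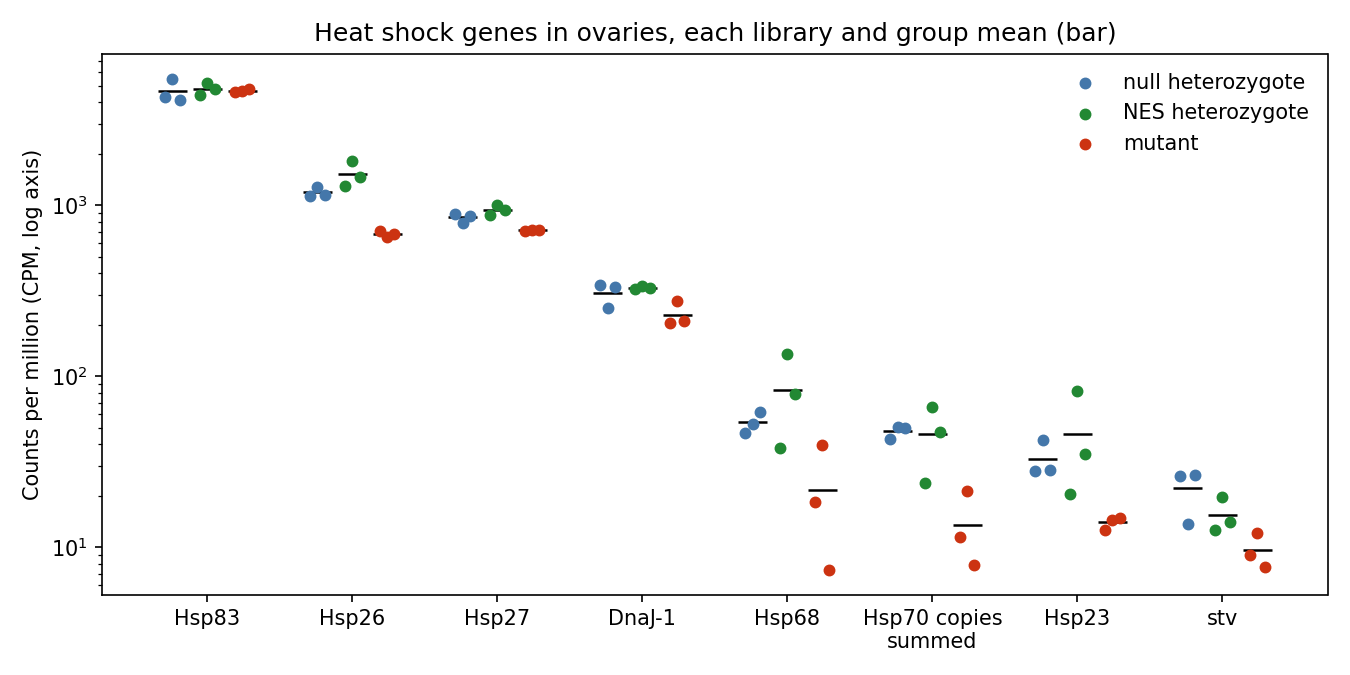
TMM-scaled CPM on a log axis (y axis) for 7 heat shock genes and the summed Hsp70 copies (x axis) in each library of the null heterozygote, NES heterozygote and mutant, with group means as bars. All 3 mutant libraries lie below all 6 heterozygote libraries for Hsp26, whose group means are 1188, 1530 and 680 CPM, while Hsp83 means lie between 4640 and 4804 CPM.

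In all, 108 genes changed between the mutant and the null heterozygote, 71 higher and 37 lower, of 8642 tested. Of these, 32 were also called the same way in the NES against the null heterozygote. For them the null heterozygote was the genotype set apart. They included CG8170, asRNA:CR45600, GstE1, GstE9, GstE6, Cyp12a4 and Cyp6a17. Cyp12a4 was at 1.05, 7.87 and 7.19 CPM in the null heterozygote, NES heterozygote and mutant. The highest included CG8170, with 0 counts in the null heterozygote and at least 70.3-fold higher in the mutant (floor of 3 counts over the group), and Hdc, the histamine synthesis enzyme, which rose by 6.20 on the log2 scale (SE 0.90, adjusted p = 0.0162). The antisense RNA gene asRNA:CR45600 had 3 counts in the null heterozygote, a ratio of 119 (95% counting interval 40.5 to 580), and CG42329 rose by 5.86 (SE 0.80). Detoxification genes were among the calls, though glutathione transferases and cytochrome P450s did not pass as lists (camera adjusted p = 0.11 and 0.222). Of 15 UDP-glycosyltransferases tested, 0 were called. GstE1, GstE9 and GstE6 rose by 1.43 (SE 0.12), 2.03 (SE 0.25) and 0.56 (SE 0.10), 3 of the 29 glutathione transferases tested. Of 44 cytochrome P450 genes, Cyp12a4 and Cyp6a17 rose by 2.78 (SE 0.18) and 2.47 (SE 0.37) and Cyp6d4 fell by 1.79 (SE 0.23). Edem1, of the endoplasmic reticulum folding list, rose by 0.31 (SE 0.06, adjusted p = 0.0352).

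Eggshell, yolk and follicle cell genes leaned higher in the mutant than in the null heterozygote as lists, with few members past the threshold. Chorion genes had a median log2 fold change of 0.98 with 9 of 9 positive (camera adjusted p = 0.000129) and 0 called. The other eggshell list had a median of 0.95 and 19 of 21 positive (adjusted p = 0.000129). Its 1 called member was Muc12Ea, which rose by 1.58 (SE 0.25, adjusted p = 0.0223). Follicle cell markers (median 0.63, 21 of 22 positive, adjusted p = 5.98e-05), muscle genes (0.56, 22 of 23, adjusted p = 0.000468) and yolk genes (0.62, 6 of 6, adjusted p = 0.043) leaned the same way, as did lipid metabolism (0.21, adjusted p = 0.0207), oxidative phosphorylation (0.10, adjusted p = 0.0207) and cytosolic ribosomal proteins (0.07, adjusted p = 0.0421). DNA replication and cell cycle genes (-0.18, adjusted p = 0.034) and piRNA pathway genes (-0.15, adjusted p = 0.0421) leaned lower. With an estimated correlation, adjusted p lay between 0.73 and 0.848 for these 10 lists. Eggshell and yolk genes took 2.73% of counts in the null heterozygote and 5.22% in the mutant. Without null heterozygote replicates 1 and 3, a set chosen after seeing the data that leaves 1 library in that group (n = 1) and takes the spread from the other groups, 19 genes were called, and the other eggshell, yolk, ribosomal, oxidative phosphorylation and DNA replication lists turned direction. With the eggshell share as a covariate the muscle and piRNA lists also turned direction (adjusted p = 0.868 and 1), as did the other eggshell, ribosomal, oxidative phosphorylation and DNA replication lists. Without replicate 2 alone, 3679 genes were called.

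The comparison of the mutant with the NES heterozygote asks what changes when the wild-type copy is replaced by the null allele. Hsp26 fell from 1530 ± 264 to 680 ± 30.1 CPM (log2 fold change -1.17, SE 0.12, adjusted p = 0.00456). Of the 17 heat shock genes tested, Hsp26 alone passed over all genes, 9 were lower when adjusted over the list alone, and 16 had a negative log2 fold change. The median was -1.16 (camera adjusted p = 2.41e-11, but adjusted p = 0.947 with an estimated correlation and 0.243 by fry). Without the Hsp70 copies it was -0.524. Hsp27, at 937 ± 61.1 and 714 ± 4.43 CPM, had a log2 fold change of -0.39 (SE 0.08, adjusted p = 0.0565), Hsp23 of -1.72 (SE 0.44) and Hsp68 of -1.95 (SE 0.60). The summed Hsp70 copies were at 23.7, 66.4 and 46.9 CPM in NES heterozygote replicates 1, 2 and 3 and at 11.5, 21.2 and 7.87 in the mutant. The groups overlapped in the mean log2 deviation of the list members from their averages, at -0.283 in NES heterozygote replicate 1 and -0.151 in mutant replicate 2. Without NES heterozygote replicate 2 the list's median was -0.51.

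Here 84 genes changed, 50 higher and 34 lower. Of these, 29 also set the NES heterozygote apart from the null heterozygote in the same way. They included CG8851, Dscam4, CR45458, lncRNA:CR44445, GstE11, GstZ1 and Cyp6t3. Dscam4 was at 22.9 CPM in the null heterozygote, near its level in the mutant. CG8851 had 0 counts in the NES heterozygote and was at least 119-fold higher in the mutant (floor of 3 counts over the group). Dscam4, a cell adhesion gene of the Dscam family, was at 0.127 ± 0.105 CPM in the NES heterozygote and 24.6 ± 0.552 in the mutant (log2 fold change 7.58, SE 0.35, adjusted p = 6.95e-05). CR45458 had 1 count and lncRNA:CR44445 had 3 counts in the NES heterozygote, with ratios of 231 (95% counting interval 41.1 to 9160) and 143 (48.7 to 697). GstE11 and GstZ1 rose by 0.87 (SE 0.11) and 0.86 (SE 0.16), and Cyp6t3 and Cyp4p1 by 4.91 (SE 0.53) and 3.12 (SE 0.49). Fbp2, of the fat body list, had 1 count in the NES heterozygote and a ratio of 56.5 (9.79 to 2260). The piRNA gene squ fell by 0.59 (SE 0.11, adjusted p = 0.0478).

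Among lists, DNA replication and cell cycle genes (median -0.21, 31 of 32 negative, camera adjusted p = 1.29e-05), RNA polymerase II transcription genes (-0.10, adjusted p = 0.0242) and mRNA export and nuclear pore genes (-0.08, adjusted p = 0.0409) were lower in the mutant than in the NES heterozygote. Cytosolic ribosomal proteins (0.12, 77 of 78 positive, adjusted p = 0.000251), muscle genes (0.44, adjusted p = 0.00107) and follicle cell markers (0.42, adjusted p = 0.00577) were higher, with 0 members of these 6 lists called. With an estimated correlation, adjusted p was 0.947 for each. Eggshell and yolk genes took 4.19% of counts in the NES heterozygote and 5.22% in the mutant. Without NES heterozygote replicate 3, 28 genes were called, and without null heterozygote replicate 2, which enters through the shared spread, 259.

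Against both heterozygotes in the same direction, 26 genes changed, 10 higher and 16 lower. By the same count, 32 genes set the null heterozygote and 29 the NES heterozygote apart from the other genotypes. The receptor gene otk2 (chromosome 2R, 12023146 to 12025272) was at 2.01 ± 0.941 CPM in the null heterozygote, 2.56 ± 0.471 in the NES heterozygote and 37.8 ± 7.50 in the mutant, with log2 fold changes of 4.24 (SE 0.37, adjusted p = 0.00162) and 3.89 (SE 0.37, adjusted p = 0.00259). The noncoding gene lncRNA:CR32368 rose by 5.54 (SE 0.79) and 5.09 (SE 0.77), and CG17264 by 3.31 (SE 0.47) and 3.96 (SE 0.49). Smaller rises were those of CR14033, an annotated pseudogene (1.195 and 0.948), CG31075 (1.104 and 1.004), CG7460 (0.98 and 0.91), dpr6 (0.80 and 0.997), Drep1 (0.79 and 0.79), CG14036 (0.63 and 0.69) and Itpr, the inositol trisphosphate receptor (0.65 and 0.65).

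The synaptotagmin gene Syt4 (chromosome 3R, 7266065 to 7270809) fell furthest among the genes lower than both heterozygotes, at 6.95 ± 1.12 and 7.41 ± 3.07 CPM in the heterozygotes against 2 counts in the 3 mutant libraries. The heterozygote to mutant ratios were 425 (95% counting interval 117 to 3520) and 452 (125 to 3740). CG11034 fell, with log2 fold changes of -2.51 (SE 0.20) and -2.53 (SE 0.20), from 25.4 ± 2.52 and 25.8 ± 2.63 to 4.46 ± 1.19 CPM. CkIIalpha-i3 fell as well (-1.97, SE 0.13, and -1.58, SE 0.13). Also lower were Pxd (-5.46 and -6.38), CG10962 (-4.66 and -4.66), mthl8 (-4.37 and -3.998), the pseudogene CR12628 (-4.20 and -4.10), Dh44-R2 (-3.12 and -3.20), CG6656 (-1.38 and -1.14), CG30440 (-0.90 and -0.75) and Hsp26. Pseudogene counts may share reads with a parent gene.

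**Figure D3:**
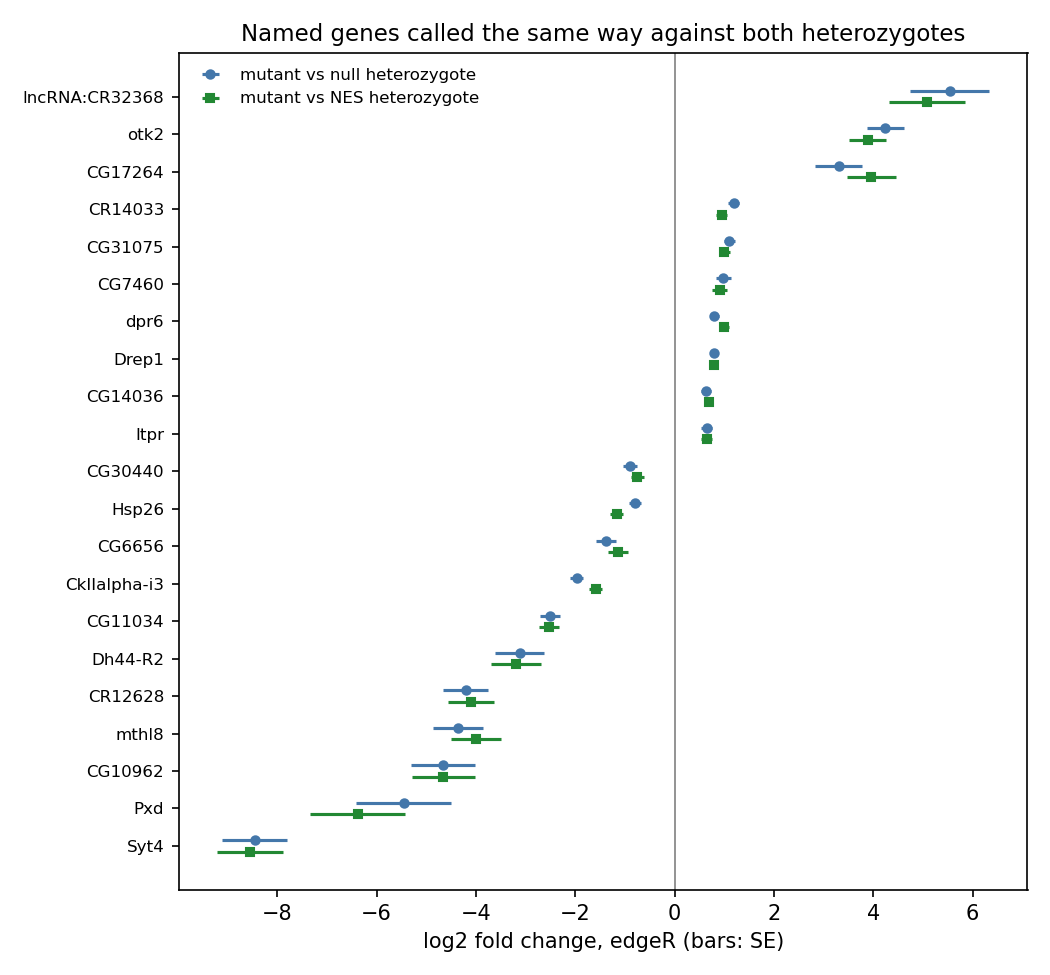
Log2 fold change of the mutant against the null heterozygote (circles) and the NES heterozygote (squares) on the x axis, with SE bars, for 21 genes (y axis) called the same way in both comparisons. The values run from -8.46 and -8.55 for Syt4, whose fitted size rests on 2 mutant counts, to 5.54 and 5.09 for lncRNA:CR32368.

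Both comparisons use the same mutant libraries. In 50 simulations with no effect, 0 genes were called in both on average and the covariance of log2 fold changes across genes was 0.0583 (highest 0.0754, observed 0.22). Their correlation averaged 0.498 with a highest value of 0.569, so the observed 0.563 lies within the range without an effect. The simulations drew each gene independently, without variation shared across genes of a library. Of 840 groupings of the real libraries, 797 gave 0 such genes, but the highest other than the real one gave 2091. The simulations therefore understate what can arise without an effect. Independent lists of the observed sizes would share 0.411 higher and 0.146 lower genes, against 10 and 16 observed. The 3 mutant libraries cannot be split into parts of at least 2, so part of the excess in called genes and covariance may come from the shared libraries. Across 20 alternative settings, CkIIalpha-i3, CG11034 and otk2 were called in 20, Syt4 in 19, Drep1, dpr6, CR12628, CR14033 and CG31075 in 18, mthl8 in 17, CG10962 in 14, Hsp26 and CG17264 in 13 and lncRNA:CR32368 in 12. Less stable were Pxd and CG14036 in 8, Itpr, Dh44-R2 and CG7460 in 7 and CG6656 and CG30440 in 6. The count of 26 genes fell to 11 without null heterozygote replicate 3 or without mutant replicate 1, and was 181 without null heterozygote replicate 2. The 1 gene called in opposite directions, named after its values were seen, was Arc1, which fell by 0.67 (SE 0.12) against the null heterozygote and rose by 0.95 (SE 0.12) against the NES heterozygote.

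The comparison of the NES with the null heterozygote measures how the 2 control genotypes differ. Here 72 genes changed, 38 higher and 34 lower in the NES heterozygote. CG8170 was at least 55.3-fold higher, and CG8851 at least 95.5-fold lower (floor of 3 counts over the group at 0). CG42613, GLaz (a lipocalin) and Hk (a potassium channel subunit) rose by 4.72 (SE 0.44), 3.08 (SE 0.40) and 3.76 (SE 0.63), and asRNA:CR45600 had a ratio of 59.5 (20 to 291). Dscam4 fell by 7.47 (SE 0.35, adjusted p = 7.75e-05). The pseudogene CR45458 and the noncoding lncRNA:CR44445 were lower by ratios of 221 (39.3 to 8780) and 84.3 (28.5 to 411). Of 29 glutathione transferases, GstE1 (1.88, SE 0.12), GstE9 (1.78, SE 0.25) and GstE6 (0.65, SE 0.10) rose, and GstE11 (-1.03, SE 0.11) and GstZ1 (-0.99, SE 0.16) fell. Of 44 cytochrome P450 genes, Cyp12a4 (2.91, SE 0.19) and Cyp6a17 (2.92, SE 0.37) rose and Cyp6t3 (-4.17, SE 0.53) fell.

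Heat shock genes showed no common direction between the heterozygotes. Their median log2 fold change was 0.06, with 10 of 17 positive, 0 called and camera adjusted p = 0.78. Chorion genes (median 0.86, 9 of 9 positive, adjusted p = 6.48e-05), other eggshell genes (0.46, adjusted p = 0.00435) and proteasome genes (0.11, 31 of 35 positive, adjusted p = 0.0194) were higher in the NES heterozygote, with adjusted p = 0.922 for each with an estimated correlation. Eggshell and yolk genes took 2.73% of counts in the null and 4.19% in the NES heterozygote. The 17 genes of Moesin partners and regulators had 0 called members in each comparison, with camera adjusted p of 0.718 against the null heterozygote, 0.672 against the NES heterozygote and 0.297 between the heterozygotes. Without null heterozygote replicates 1 and 3, which leaves n = 1 in that group, 32 genes were called between the heterozygotes and the 3 called lists turned direction; without replicate 2, 741 genes were called, and without replicate 3, 35.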

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

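The eggshell covariate and leaving out null heterozygote libraries 1 and 3 were chosen after the results were seen. Values are given for the mutant against the null heterozygote, against the NES heterozygote, between the heterozygotes and against both, in that order. The cause of a change was not tested unless stated. Genes called were 506, 319, 306 and 130 with DESeq2; 61, 27, 33 and 12 with the stricter filter, which tests fewer genes; 51, 145, 24 and 15 with only the groups compared; 40, 26, 29 and 9 against a 1.5-fold change, a stricter question; 817, 1081, 2429 and 155 with the eggshell covariate. Without null heterozygote libraries 1 and 3, which leaves n = 1 in that group with its spread taken from the other groups, they were 19, 32 and 10 for the first comparison, between the heterozygotes and against both. Leaving out 1 library gave 26 to 3679, 28 to 259, 35 to 741 and 11 to 181, the upper end each time without null heterozygote replicate 2. Counts under DESeq2's size factors, scaling without eggshell genes, library size alone and no filter stayed within 1.5 times.

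Replicate numbers did not pair the samples: 2 of 9 same-number pairs had a correlation of deviations over 0.1 (range -0.452 to 0.48), and 4 libraries correlated best with their own number. With the replicate number as a block, 59, 34, 38 and 16 genes were called. The heat shock list changed direction between the heterozygotes under the block (adjusted p = 0.997).

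Lists called fell to 0, 0 and 0 with an estimated correlation and likewise 0, 0 and 0 by fry's directional test. The heat shock list's adjusted p was 0.73 and 0.947, and 0.155 and 0.243, against the 2 heterozygotes. Fry's mixed test, for changes in either direction, passed for glutathione transferases and cytochrome P450s in all 3 comparisons (adjusted p at most 2.36e-05 and 0.00441). It also passed for neurons against the null heterozygote (0.0395), fat body against the NES heterozygote (0.0143) and UDP-glycosyltransferases between the heterozygotes (0.00687). For heat shock genes it gave 0.0395 and 0.0241 against the 2 heterozygotes. By camera the heat shock list stayed lower without any 1 library, with adjusted p from 6.49e-11 to 0.000279 and from 2.41e-25 to 6.08e-07, and under the block and the covariate. With the 1 null heterozygote library left without libraries 1 and 3, its median against that group was -0.649, against -0.967 with all libraries. Lists called with 1 library left out were 5 to 17, 3 to 10 and 3 to 12; between the heterozygotes they were 7 with the covariate and 7 without libraries 1 and 3. Between the heterozygotes the heat shock list's adjusted p ranged from 0.103 to 0.942 and its median from -0.207 to 0.176, and it changed direction without NES heterozygote replicate 2 and without null heterozygote replicate 2.

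With the eggshell covariate, these lists changed direction against the null heterozygote: DNA replication (adjusted p = 8.65e-06), cytosolic ribosomal proteins (0.000471), oxidative phosphorylation (0.00132), other eggshell genes (0.194), muscle (0.868), piRNA pathway (1) and Moesin partners (1). Between the heterozygotes, other eggshell genes (0.0165) and proteasome (0.46) did. The eggshell lists make up the covariate, so their values there follow from its construction. Log2 fold changes became 0.138 for Hsf, -0.216 for Hsp83 and -0.133 for Moe against the null heterozygote.

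Without null heterozygote libraries 1 and 3, lists that changed direction against the null heterozygote were cytosolic ribosomal proteins (3.5e-07), oxidative phosphorylation (0.000839), DNA replication (0.00189), other eggshell genes (0.684) and yolk (0.912). Between the heterozygotes they were other eggshell genes (0.0171), proteasome (0.322) and chorion (0.704). Log2 fold changes against the null heterozygote became 0.117 for Hsf, -0.246 for Hsp83, -0.112 for Moe, -0.003 for LpR2, -0.07 for RpS2, -0.037 for RpS25, -0.027 for Yp1, -0.048 for Yp2 and -0.075 for clos.

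With library size alone Hsp83 was at -0.036 against the null heterozygote. With 1 library left out, values changed sign within these ranges: Hsp83 -0.073 to 0.153 and Hsp67Ba -0.39 to 0.234 against the null heterozygote; Hsp83 from -0.095 to 0.022, Hsp67Bc -1.301 to 0.135 and Tsf1 -0.045 to 2.47 against the NES heterozygote. None of these genes was called in the comparison concerned. Of the other values of named genes, 3612 kept side and direction, 356 lost the call and 145 gained one; of called lists and the heat shock and Moesin lists, 265 kept it and 83 lost the call. Of 1280 values of lists not described singly, 131 changed direction, 9 of them past the threshold; of 334 such values of genes, 25 did, 1 past it. Counts as low as those of Hsp67Ba limit what can be called.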

Other observations

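Chosen only after the results were seen were the tests of the Hsp70 copies, of separate heat shock loci, of nearly silent genes and of the sum of both heterozygotes, the fit with the eggshell share as a covariate, the 24 tests by chromosome and the 3 tests near Moe. The prediction for the covariate fit was written before its result, but the rule that a median must pass its bound by 1 SE was added after the medians were seen. Tests of other groupings were planned, except the count over every grouping of the 9 libraries.

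With the eggshell share as a covariate, edgeR called 155 genes the same way against both heterozygotes, 76 higher and 79 lower, and these held all 26 of the genes called without it. Of 17 heat shock genes, 5 were lower against the null heterozygote and 9 against the NES heterozygote. Over all 8642 genes tested, 288 and 568 were lower. Hsp26 was at -0.995 (adjusted p = 0.000405) and -1.21 (adjusted p = 6.71e-06), and Hsp23 at -1.89 (adjusted p = 0.0173) and -1.78 (adjusted p = 0.00479). In that fit 25 of 32 DNA replication genes were higher and 23 of 78 cytosolic ribosomal protein genes lower in the NES than in the null heterozygote. Over all 8642 genes, 1488 were higher and 941 lower. Eggshell shares were 0.903%, 4.133% and 1.07% in null heterozygote replicates 1, 2 and 3, and 3.124% to 4.761% in the mutant. At the mutant's share that group thus rests mainly on replicate 2. The covariate fit and leaving out replicates 1 and 3 are therefore not separate checks. Of lists that other tissue in a dissection would bring, muscle had medians of 0.56 and 0.44 against the null and NES heterozygotes without the covariate (camera adjusted p = 0.000468 and 0.00107, but adjusted p = 0.756 and 0.947 with an estimated correlation). With the covariate it changed direction against the null heterozygote (adjusted p = 0.868) and kept it against the NES heterozygote (adjusted p = 0.0218). Fat body, without the covariate, had medians of 0.65 and 0.36, with 11 and 10 of 13 positive (adjusted p = 0.0949 and 0.197) and Fbp2 called against the NES heterozygote. Adjusted p was 0.242 and 0.0896 for hemocytes and 0.242 and 0.548 for neurons. A different share of other tissue is not excluded.

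By chromosome, called genes against the NES heterozygote were most frequent on 2L, 26 of 1481 (Fisher's exact test, adjusted p = 0.0254 over 24 tests), and between the heterozygotes least frequent on 3L, 4 of 1623 (adjusted p = 0.0254). Within 1 Mb of Moe, 5 of 162 genes were called against the NES heterozygote, Moe among them (Fisher's exact p = 0.0205, unadjusted), 2 against the null heterozygote (p = 1) and 2 between the heterozygotes (p = 0.392). CG10962 (chromosome X, 8972908 to 8974255), lower against both heterozygotes, was among them in both mutant comparisons. Whether its change is tied to its place near Moe was not tested. The counts against the NES heterozygote and between the heterozygotes include Moe itself, the gene that the genotypes alter. Those tests therefore decide nothing about its neighbours.

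Other groupings of the libraries bear on chance. The 10 splits of 6 libraries are too few for a share under 0.05. Against the null heterozygote 2 splits gave at least the real 108 genes, the real one included, with 1628 as the highest other; against the NES heterozygote 1 did, with 84 and 0; between the heterozygotes 2 did, with 72 and 2453. The splits with 1628 and 2453 genes set null heterozygote replicates 1 and 3 with mutant replicate 2 or NES heterozygote replicate 1, and so point to a structure of the samples that crosses the genotypes. For the 26 genes called against both heterozygotes, 4 of 100 groupings of the 9 libraries (the real one and 99 drawn at random) gave as many, with 2091 as the highest other, too few draws to decide. Over all 840 groupings 14 did (1.67%), the real one included, which argues against chance alone. Of these 14, 10 set null heterozygote replicates 1 and 3 with NES heterozygote replicate 1, the same structure. With genotypes kept whole, 32 genes set the null heterozygote and 29 the NES heterozygote apart from the other genotypes, so the 26 of the mutant do not make it stand out.

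The heat shock list was lower in the mutant by camera, with 1 of 17 members called over all genes in each comparison, but adjusted p was 0.73 and 0.947 with an estimated correlation and 0.155 and 0.243 by fry. With the eggshell share as a covariate, the list's medians were -0.995 (SE between libraries 0.487) and -1.132 (SE 0.377). Both lay below the bound of -0.5 set beforehand, but the first by little more than 1 SE. The covariate measures eggshell transcripts only. Without null heterozygote libraries 1 and 3, which leaves n = 1 in that group, the median against it was -0.649. A different mix of egg chamber stages is therefore argued against weakly and is not excluded. Reads split among Hsp70 copies cannot account for all of the list's lean, since the other members had medians of -0.422 and -0.524 (SE 0.171 each). With the copies the medians were -0.967 and -1.156, so much of the lean's size comes from them. This comparison was chosen after the members were seen to be negative. The summed copies stayed lower by more than 2 SE but were not called (edgeR adjusted p = 0.0974 and 0.13). A sum does not recover reads lost because they map to several copies. Variants of the parental stocks, in cis at separate loci or a single one in trans, remain open: a sign test over separate loci decides nothing, because it ran on members already seen to be negative in the same mutant libraries. The genotype and its stock background cannot be separated in this design, so an effect of Moe is a hypothesis only.

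Some genes were nearly silent in 1 genotype, with every library of it more than 5-fold below every other library. There were 21, with 7 in the null heterozygote, 9 in the NES heterozygote and 5 in the mutant. If each genotype came from a direct cross of 2 of 3 stocks, an assumption not checked here, it lacks 1 of the 3 parental haplotypes. Haplotypes of the 3 stocks may then account for such genes. The mutant did not hold an excess (one-sided exact binomial p = 0.879). The haplotype explanation needs equal levels in the other genotypes, and the median absolute log2 ratio was 0.314, with Syt4 at 0.09 and Dscam4 at 0.10. Osi17 at 2.005, CG44153 at 1.455 and CR33319 at 1.428 do not meet it. Also unequal were asRNA:CR45600 at 0.991, Pxd at 0.916, Cyp6t3 at 0.735 and lncRNA:CR44445 at 0.724. The count includes w, a usual marker of transgenes, and a p that misses the threshold does not show equal shares.

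Of the 10 genes higher in the mutant than in both heterozygotes, 3 were above the sum of the heterozygote levels by more than 2 SE: otk2, CG17264 and lncRNA:CR32368, at 8.29, 6.1 and 20.1 times the sum. Under the same assumed crosses, additive haplotypes of the parental stocks allow at most the sum, so these 3 argue against them. A recessive or interacting variant, or an effect of Moe, was not tested. The other 7 reached at most 1.05 times the sum, so for them additive haplotypes and an effect of the mutant genotype cannot be told apart, since they were picked for not lying above it by more than 2 SE. CR14033, CG31075, CG7460 and dpr6 lay within 2 SE of the sum. Genes nearly confined to 1 genotype were the same 3, all in the mutant and 0 in either heterozygote (one-sided exact binomial p = 0.037, on genes already seen to be high there).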
